A study of Bombyx mori with 5 samples.

How the data were processed

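Small RNAs bound to PIWI proteins were sequenced from BmN4 cells, an ovary-derived cell line of the silkworm Bombyx mori. PIWI proteins carry piRNAs, small RNAs that guide them to transposon transcripts. Siwi and BmAGO3 are the PIWI proteins studied here, and they are known to feed each other with new piRNAs in the ping-pong cycle, in which each protein cuts a target opposite position 10 of its guide. Per the labels' protocols, cells were grown at 27 °C, protein complexes were captured with antibodies on magnetic beads and washed with 500 mM sodium chloride, and libraries were made with a small RNA kit. The 5 libraries fall into 5 groups of 1: endogenous Siwi and endogenous BmAGO3 from untreated cells, and Flag-tagged Siwi from cells treated with Luc, Vasa or BmAGO3 siRNA. Luc siRNA, directed against luciferase, is the control. Vasa is a DEAD-box RNA helicase of the germ line.

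Each deposited file lists distinct small RNA sequences with a raw count of reads, and the authors listed no sequence with fewer than 10 reads. This was checked on the values, since the files have no header. Bowtie2 is named in the submitters' processing notes, without a version; adapter trimming, length limits and the genome build are not given in the sources used here. The lists differ between the batches of files in ways that precede any comparison here. Sequences reach 32 and 33 bases in the untreated libraries and 40 or 41 bases in the Flag-Siwi libraries, and sequences with uncalled bases occur in the untreated libraries and not in the Flag-Siwi ones. Listed reads numbered 945195 for untreated Siwi, 1735641 for untreated BmAGO3, 1313629 for Luc siRNA, 3378654 for Vasa siRNA and 1492489 for BmAGO3 siRNA. These totals leave out all sequences below 10 reads and are not the full depth of sequencing. An unlisted sequence had at most 9 reads, so a fold against an unlisted sequence is a lower bound.

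From the counts, shares of listed reads were computed for each length, for U at position 1 (1U) and for A at position 10 (10A), counted from the 5′ end. Sequences are printed in the DNA alphabet of the files, with T for U. Shares carry Wilson 95% binomial intervals and differences of shares carry Newcombe intervals. Reads without molecular identifiers are not independent molecules, so all intervals cover counting error only. With 1 library per group there is no replicate check on any difference and no p-value was computed; every comparison is between libraries, not between conditions. A ping-pong partner was called by the first 10 bases of a sequence of at least 20 bases. These had to be the reverse complement of the first 10 bases of a sequence in the partner library. Forms with the same 5′ end thus share their partner status. Intervals of partner shares count such forms as independent and can be too narrow. The same 10-base key was moved to 5′ overlaps of 11 to 20 bases to give a background level. At 10 bases, 1U of Siwi faces 10A of BmAGO3, so base composition alone favors matches between the proteins there. At the other overlaps these positions do not face each other, so the background is not an exact chance level. The size of this effect was not computed.

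Abundance was compared as the log2 ratio of reads per 1000000 listed reads (RPM), with a pseudocount of 1 read. Sequences with at least 100 reads summed over both libraries were used. This limit is on raw reads and is reached at a lower RPM in the deeper library, which favors sequences higher there. Unlisted sequences entered with 9 reads. Folds of single sequences are ratios of RPM without the pseudocount, with exact Clopper-Pearson intervals. Medians of sequence classes, which leave out tRNA-like sequences except in the tRNA-like class, were given relative to the median of all sequences and placed among 10000 random lists of the same size matched on abundance. Named sequences were chosen by a rule fixed before the data were examined: the 5 most abundant of each library, and the 5 highest and 5 lowest log2 ratios of the BmAGO3 against Siwi, Vasa siRNA and BmAGO3 siRNA comparisons whose interval excluded 1. The same rule added detected members of a list of 20 insect microRNAs, matched by their first 15 bases, and of transposon lists.

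A tRNA-like class was defined after the data were seen, as sequences with an A-box motif starting in the first 12 bases or a B-box motif; these are the internal promoter elements of tRNA genes. In sequences with shuffled bases the motifs took 0.192% of reads of untreated Siwi and 0.166% of untreated BmAGO3, against 0.225% and 0.0838% in the sequences as listed, and between 0.0796% and 0.211% in the Flag-Siwi libraries. The class totals of the untreated libraries are thus no larger than chance hits could make them, or little larger. This does not make each member a chance hit. Sequences that begin with TCTTCGGTAG held 66.3% of the tRNA-like reads of the Luc siRNA library. They also held 35.5% of those of untreated Siwi and 58.9% of those of untreated BmAGO3. Alternatives fixed beforehand were other weights, length limits, read minimums, scalings, pseudocounts and grouping by the first 20 bases, also with thinned libraries. Leaving out tRNA-like sequences and the other thinning of libraries were added after the data were seen. Values without tRNA-like sequences leave out only sequences with a motif, so tRNA fragments without one can remain. Transposon and strand of origin, the transposon lists and tRNA gene annotation were not analysed here, because no genome or transposon sequence was used. Knockdown of Vasa or BmAGO3 was not measured by these small RNA libraries.

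Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and TMM scaling came from edgeR 4.0.16. The ratio step was tested on simulated data drawn for the BmAGO3 siRNA against Luc siRNA comparison. Of 100 sequences planted with a 4-fold change, 100% came out at least 2-fold changed, as did 1 of 4264 unchanged sequences. The simulated counts held counting error and no variation between libraries, and these ratios were centered on their median. The main counts of changed sequences are not centered, so the simulation gives no error rate for them. The 95% intervals held the true ratio for 96.1% of the unchanged sequences. In a simulation of 19000 Siwi sequences, a planted partner share of 24.996% was read as 26.8%, with a mean of 2.51% at overlaps of 11 to 20 bases.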

Results

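Small RNAs were read from 5 immunoprecipitates of BmN4 cells, 1 per group. The lists held 19065 distinct sequences for untreated Siwi, 19134 for untreated BmAGO3, 22101 for Flag-Siwi with Luc siRNA, 41691 with Vasa siRNA and 24017 with BmAGO3 siRNA. Listed reads ranged from 945195 for untreated Siwi to 3378654 for the Vasa siRNA library. Reads of 24 to 32 bases, the length of piRNAs, made up between 97.1% and 99.2% of each library. The 10 most abundant sequences took from 5.53% of reads in untreated Siwi to 14.2% in the BmAGO3 siRNA library. No group had a replicate, so none of the differences given here has a replicate check.

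Siwi and BmAGO3 from untreated cells held small RNAs of different length and base composition. Siwi reads peaked at 28 bases, which made up 49.4% of reads, and BmAGO3 reads at 27 bases, with 42.4%. Siwi reads began with U in 91.3% of cases (95% interval 91.3% to 91.4%), and BmAGO3 reads in 35.8% (35.7% to 35.8%). In BmAGO3, A and C were also frequent at the first position, with 33.2% and 24.6% of reads, while G took 6.28%. A at position 10 was found in 79.7% of BmAGO3 reads (79.7% to 79.8%) and in 29.8% of Siwi reads (29.7% to 29.9%). The differences of BmAGO3 from Siwi were -55.6 points for 1U and 49.9 points for 10A. The mean length was 26.7 bases for BmAGO3 and 27.6 bases for Siwi. Among 68 5′ ends with at least 100 reads in each library, the BmAGO3 forms differed from the Siwi forms by -0.596 bases on average (SD 0.573 over 5′ ends), and 86.8% of these ends had shorter forms in BmAGO3.

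**Figure D1:**
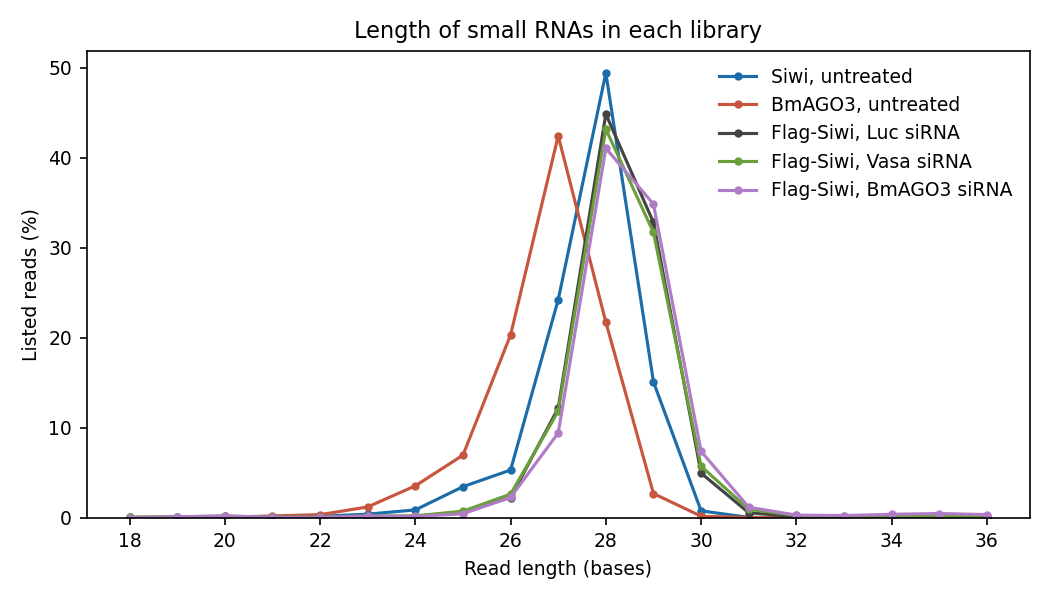
Percent of listed reads (y axis) at each read length in bases (x axis) for the 5 libraries, 1 line per library. BmAGO3 peaks at 27 bases and the other libraries at 28 bases; the Flag-Siwi libraries hold more reads of 29 bases (32.8%, 31.7% and 34.8% for Luc, Vasa and BmAGO3 siRNA) than untreated Siwi (15.1%).

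**Figure D2:**
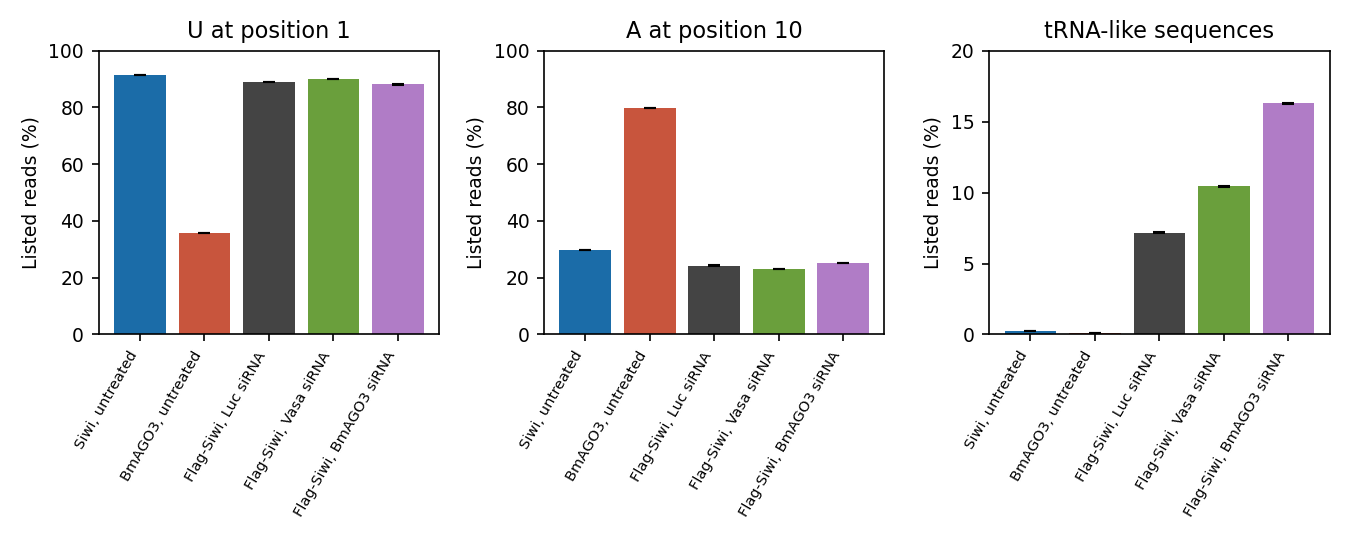
Percent of listed reads with U at position 1, with A at position 10, and in tRNA-like sequences (y axes, the last one on a shorter scale), for the 5 libraries; bars are shares and error bars are Wilson 95% intervals. BmAGO3 differs from the Siwi libraries in the first 2 panels, and tRNA-like reads reach 7.17%, 10.5% and 16.3% in the Luc, Vasa and BmAGO3 siRNA libraries.

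Siwi and BmAGO3 sequences paired with each other at the 10-base overlap of the ping-pong cycle. Of 19024 Siwi sequences, 24.4% (23.8% to 24.98%) had a BmAGO3 partner at 10 bases, against a mean of 2.10% at overlaps of 11 to 20 bases. Of 19028 BmAGO3 sequences, 27.8% (27.2% to 28.4%) had a Siwi partner, against 2.50%. Pairs within 1 protein were rarer, at 6.23% for Siwi with Siwi and 8.46% for BmAGO3 with BmAGO3. Base composition at positions 1 and 10 by itself favors pairs between the proteins, to an extent not computed here.

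**Figure D3:**
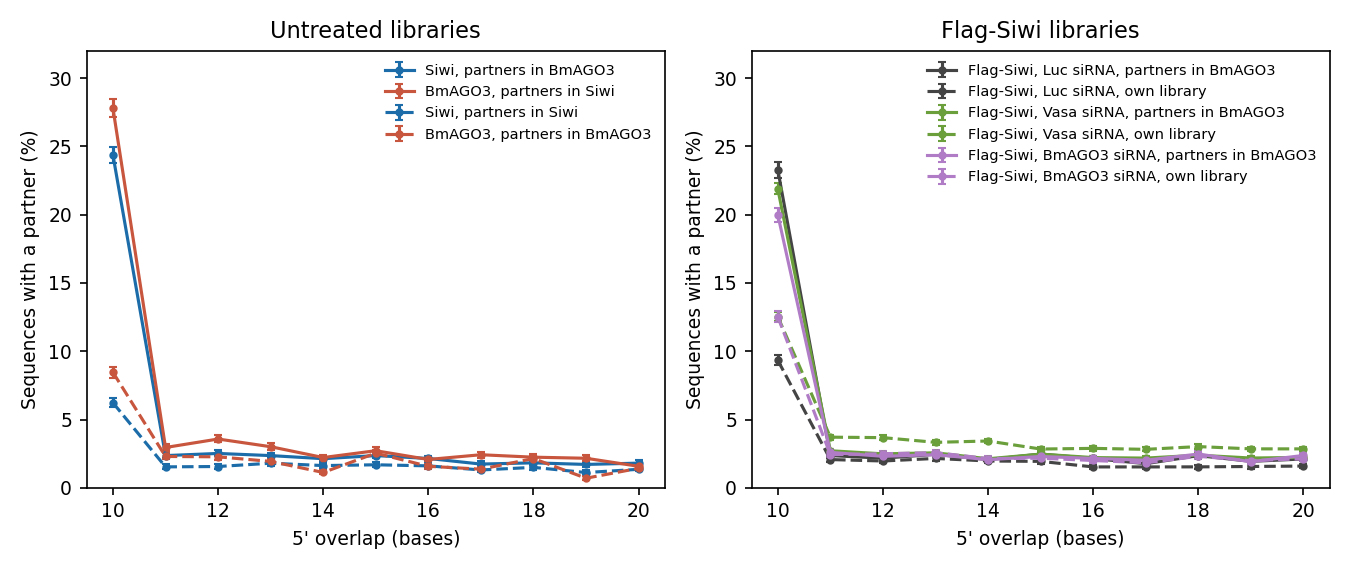
Percent of sequences with a partner (y axis) at 5′ overlaps of 10 to 20 bases (x axis), for the untreated libraries (left) and the Flag-Siwi libraries (right). Solid lines show partners in the other protein's untreated library and dashed lines partners in the same library; error bars are Wilson 95% intervals. All curves are highest at 10 bases, up to 27.8% for BmAGO3 with Siwi partners.

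The lists of the proteins shared 1348 sequences, 7.07% of the Siwi list and 7.05% of the BmAGO3 list, with 24.8% of Siwi reads and 28.0% of BmAGO3 reads. By the first 20 bases, shared reads were 35.9% and 39.3%. The untreated Siwi and Luc siRNA lists, both of Siwi, shared 38.1% and 32.8% of their sequences, and an unlisted sequence is not an absent one. Of 4126 sequences with at least 100 reads, 2137 were listed for BmAGO3 only, 1305 for Siwi only and 684 for both. RPM was at least 2-fold higher in BmAGO3 for 2366 sequences and in Siwi for 1698. Leaving out tRNA-like sequences, 2405 of these began with U, and their median log2 ratio of BmAGO3 to Siwi was -4.40, while it was 3.29 for the 1712 that began with another base; unlisted sequences entered these medians at their bound. Among the sequences listed for both proteins, without a read minimum, 260 were higher and 754 lower in BmAGO3. The BmAGO3 list, with more reads, reaches lower RPM than the Siwi list, which by itself favors lower ratios in this set. For the 4126 sequences the limit of 100 raw reads is reached at lower RPM in BmAGO3. This by itself favors the counts of 2137 and 2366 over those of 1305 and 1698.

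The most abundant BmAGO3 sequences were rare in Siwi. CACTGCGAGACTTCGGCGTACGTTGA led the BmAGO3 library with 15844 RPM and was 535-fold higher than in Siwi (370 to 805). AACTTCAGTACTGCGGCTTTGAACGGC, with 11674 RPM, was 649-fold higher (405 to 1114). TTGGGATATATTATCTGAAAGACTTAC, AGAGGAATTTAGAAATAGAAAAAGAGT and CTGGATCTGATGACGAAAACAGCGAATC were unlisted for Siwi and at least 735-fold, 596-fold and 474-fold higher in BmAGO3. Summed over forms with the same first 20 bases, CACTGCGAGACTTCGGCGTACGTTGA was 302-fold higher and CTGGATCTGATGACGAAAACAGCGAATC 224-fold higher. CAGTAAGTCAGAACTCGCTGAAAGAGT, second in BmAGO3 with 14571 RPM, had 10 partner sequences in Siwi with 1337 reads together. ACCAACTGTCCCTCCTCCACGTGTACGT had 9924 RPM in BmAGO3 and 54.0 in Siwi. TTACTTATAACGAACGCTGATCCGTCC, which begins with U, had 7324 and 215.

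The Siwi library was led by TATCGGAACGAACGGTTCGACAAGTAGT, with 13160 RPM against 45.5 in BmAGO3, and its shorter form TATCGGAACGAACGGTTCGACAAGT, with 6781 against 81.8. TTGCTCTAAAAACTCTTTTGTTCTGTGC had 7812 against 31.1, AACTCAAGACACAAGATCGCGACGGCAGC 5633 against 22.5, and TTCATCTGTATAAAATTGCGACCTCGTG 4942 against 24.8. The 5 sequences most depleted from BmAGO3 were all unlisted there and all began with U. TATCGGAACGAACGGTTCGACAAGTAG and TCCTTCTGTATGACTGAAGATAATTCTGT were at least 714-fold and 636-fold higher in Siwi. TGTTTCGGATTAAGCATGCTATGCTACG, TTCTGTACTATGAATTTTGGAAGGACGT and TAGCAACGTGGACTGAGATATTGAGAGT were at least 379-fold, 378-fold and 328-fold higher. Summed over forms with the same first 20 bases, TATCGGAACGAACGGTTCGACAAGTAG was 215-fold higher in Siwi.

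Flag-Siwi from Luc siRNA cells was set beside untreated Siwi to show how far 2 Siwi libraries without loss of a piRNA factor differed. Both began mainly with U, in 89.0% of Luc siRNA reads and 91.3% of untreated reads, and 10A was found in 24.3% and 29.8%, a difference of -5.53 points. With each distinct sequence counted once, the differences were -5.36 points for 1U, in place of -2.38, and -0.890 for 10A. Sequences listed for untreated Siwi carried 59.9% of Luc siRNA reads, and those listed for Luc siRNA carried 68.6% of untreated Siwi reads. Forms with the same first 20 bases were on average 0.422 bases longer in Flag-Siwi (SD 0.485, 748 5′ ends). Partners in BmAGO3 were found for 23.3% of Luc siRNA sequences, against a mean of 2.19% at other overlaps. Of 3770 sequences, 1479 were at least 2-fold higher and 1548 at least 2-fold lower in Flag-Siwi, with a median log2 ratio of -0.12. Median-ratio scaling gave 1676 higher and 1272 lower and TMM 1688 and 1260, so that higher sequences made up 56.9% or 57.3% of the changed ones in place of 48.9%. The untreated leader TATCGGAACGAACGGTTCGACAAGTAGT had 2135 RPM in the Luc siRNA library, and AACTCAAGACACAAGATCGCGACGGCAGC had 10805.

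tRNA-like sequences marked the Flag-Siwi libraries. They took 7.17% of Luc siRNA reads (7.12% to 7.21%), while in untreated Siwi and BmAGO3 they took 0.225% and 0.0838%. The sequences that begin with TCTTCGGTAG took 4.75% of Luc siRNA reads, 0.0798% of Siwi reads and 0.0493% of BmAGO3 reads. TCTTCGGTAGTATAGTGGTCAGTATCCCC was the most abundant sequence of all 3 Flag-Siwi libraries, with 19593, 28643 and 33994 RPM under Luc, Vasa and BmAGO3 siRNA, against 248 in untreated Siwi. In the Luc siRNA library 90.7% of tRNA-like reads were 27 to 30 bases long. The next Luc siRNA sequences were TAAACGGATGCGATGACGATCGGCTGGTG, TAATGTCGATGCGCCACTTCCGGAACCAC and TGACTGCAAAATAGGTGATTCTTGATGC, with 18019, 12358 and 10823 RPM against 108, 170 and 81.5 in untreated Siwi. The fifth, AACTCAAGACACAAGATCGCGACGGCAGC, had 10805 against 5633. Tag, antibody, siRNA treatment and batch of files all differ between these libraries and cannot be told apart.

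Vasa siRNA was compared with Luc siRNA to ask how Siwi-bound piRNAs depend on Vasa. Sequences listed under Vasa siRNA carried 96.7% of Luc siRNA reads. In the longer Vasa siRNA list, 46.7% of sequences, with 88.5% of reads, were also listed under Luc siRNA. Reads began with U in 90.0% against 89.0% of cases, and 10A was found in 23.1% against 24.3%. The 10A difference of -1.17 points was -0.394 without tRNA-like sequences. The mean length over all reads differed by -0.0898 bases, by -0.231 with each distinct sequence counted once and by -0.0498 with libraries thinned to equal reads. Forms with the same 5′ end differed by 0.0284 bases on average (SD 0.155, 1827 5′ ends). tRNA-like reads were higher, at 10.5% (10.4% to 10.5%) against 7.17%, a difference of 3.29 points that was 0.991 without the 10 most abundant sequences of each library and 0.282 with each distinct sequence counted once. Reads under 18 bases took 1.14% against 0.420%.

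BmAGO3 partners were found for 21.9% of Vasa siRNA sequences, a difference of -1.39 points from Luc siRNA (interval -2.08 to -0.705). Weighted by reads the difference was 0.112 points in the other direction, and with libraries thinned to equal reads it was 2.26 points in that direction. Partners within the same library were found for 12.5% under Vasa siRNA and 9.34% under Luc siRNA, a difference of 3.19 points (2.69 to 3.69), which became -0.598 after thinning. At overlaps of 11 to 20 bases the own-library means also differed, at 3.14% and 1.78%. For partners in the untreated Siwi library the difference was -0.301 points (-0.700 to 0.0911). The 1U difference of 0.981 points became -1.34 when each distinct sequence was counted once.

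Of 6753 sequences, 515 were at least 2-fold higher and 902 at least 2-fold lower under Vasa siRNA. Median-ratio scaling took the center of the log2 ratios to lie at -0.36 and TMM at -0.32. Subtracting these raised every ratio, and the counts became 1236 higher and 584 lower, or 1122 and 611, so that the share of higher among changed sequences was 67.9% or 64.7% in place of 36.3%. Both centers came from all sequences listed in both libraries without a read minimum, where the deeper Vasa siRNA list has the lower RPM floor. The 6753 sequences themselves had a median log2 ratio of 0.023. Relative to that median, 488 were at least 2-fold higher and 938 at least 2-fold lower. The direction that prevailed thus depended on the set of sequences used for scaling. Relative to all sequences, the median log2 ratio was 0.55 for 159 tRNA-like sequences, beyond all random lists. It was 0.12 for 68 sequences listed for untreated BmAGO3 and not for Siwi, at percentile 69.8 of random lists, and -0.075 for 2909 sequences listed for Siwi and not for BmAGO3, below all random lists. Among sequences listed in both libraries, without a read minimum, the last 2 medians became -0.067 and 0.063. The lower RPM floor of the Vasa siRNA list may bear on these medians as well.

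The highest sequences under Vasa siRNA included 2 forms with the same 5′ end. TGATTACTGATGTTAGGACGTTACCGTGT and its form without the last base, TGATTACTGATGTTAGGACGTTACCGTG, were 8.70-fold (4.78 to 17.6) and 7.06-fold (4.92 to 10.5) higher, and all forms with these first 20 bases were 9.09-fold higher. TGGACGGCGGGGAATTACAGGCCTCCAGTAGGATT was 8.09-fold higher (4.31 to 17.1). ACGGGAACCA, of 10 bases, and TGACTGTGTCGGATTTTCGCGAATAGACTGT were unlisted under Luc siRNA and at least 7.65-fold and 6.35-fold higher, though all forms with the first 20 bases of the latter were 1.55-fold higher. The lowest were TACAGACTATTCCGAGCCCCGACATCGG, 43.8-fold lower (30.1 to 66.1), TGTAAAGTGATATCCGGTCTATTGTAGG, 39.5-fold lower (21.5 to 80.7), and 3 sequences unlisted under Vasa siRNA: TGTATGCGTTAGAACACTGCAGAACGTGG, at least 43.4-fold lower, and CCGGACAAATTTCGCGAACATCGCGGGGG and TCTCGTGTCGTGCCGCTTTATCGAAGG, each at least 38.3-fold lower. All 5 end in G. Summed over forms with the same first 20 bases, they were 4.11-fold, 1.68-fold, 1.72-fold, 4.32-fold and 1.79-fold lower.

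BmAGO3 siRNA was compared with Luc siRNA to ask how Siwi-bound piRNAs depend on BmAGO3. Sequences listed for untreated BmAGO3 and not for Siwi, whose median was 21 reads in that library, took 1.73% of reads (1.71% to 1.75%), against 0.721% under Luc siRNA (0.706% to 0.735%), a ratio of 2.40 (2.34 to 2.45). For the 2137 of them with at least 100 reads in untreated BmAGO3 the ratio was 2.70 (2.58 to 2.84). Under Vasa siRNA the same set took 0.792%. The set listed for Siwi and not for BmAGO3 took 37.9% of reads, against 46.1% under Luc siRNA. These are shares of all listed reads, and the set itself holds some tRNA-like sequences. tRNA-like reads took 16.3% against 7.17%, which by itself lowers the shares of other sequences. BmAGO3-only here names sequences listed for untreated BmAGO3 and not for untreated Siwi. Without tRNA-like ones, 59 of them had at least 100 reads summed over the Luc and BmAGO3 siRNA libraries. Of these 59, 46 were at least 2-fold higher relative to the median of all sequences and 0 were 2-fold lower. Their median was 1.38 on the log2 scale relative to all sequences, and no random list reached it; without a read minimum, among sequences listed in both libraries, it was 0.89. The Siwi-only median was -0.20.

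**Figure D4:**
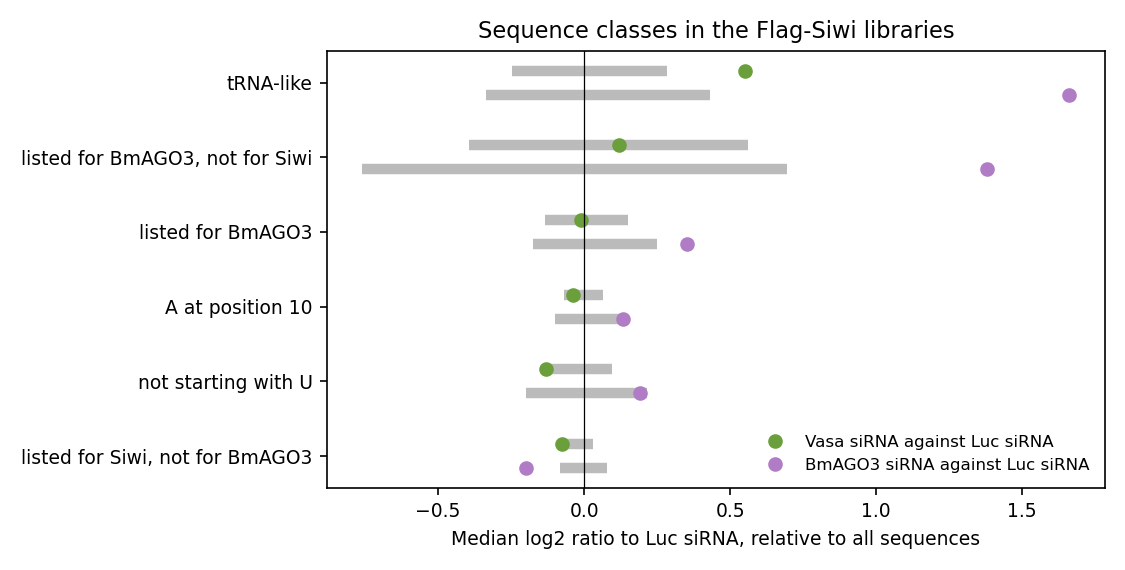
Median log2 ratio to Luc siRNA relative to all sequences (x axis) for 6 sequence classes (y axis), under Vasa siRNA (green) and BmAGO3 siRNA (purple); grey bars span the medians of 10000 random lists of the same size and abundance. tRNA-like sequences lie at 0.55 and 1.66, and sequences listed for BmAGO3 and not for Siwi at 0.12 and 1.38; without a read minimum the last 2 become -0.067 and 0.89.

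Pairing moved in opposite directions with the partner library. Of the BmAGO3 siRNA sequences, 19.99% had a partner in the untreated BmAGO3 library, a difference of -3.28 points from Luc siRNA (interval -4.04 to -2.53), or -1.33 with libraries thinned to equal reads. Partners in the same Flag-Siwi library were found for 12.5% (12.1% to 13.0%), 3.19 points more than under Luc siRNA (2.62 to 3.76). At overlaps of 11 to 20 bases the own-library means were 2.21% and 1.78%. Partners in the untreated Siwi library were found for 7.63%, against 6.27% under Luc siRNA, a difference of 1.36 points (0.892 to 1.82). Reads began with U in 88.1% of cases, a difference of -0.849 points from Luc siRNA, and 10A was 0.856 points higher, at 25.1%; without tRNA-like sequences 10A was 29.9% against 26.1%. With each distinct sequence counted once, the differences were -4.59 points for 1U and 2.75 points for 10A.

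tRNA-like reads reached 16.3% (16.2% to 16.3%) under BmAGO3 siRNA, 9.11 points above Luc siRNA. Without the 10 most abundant sequences of each library the difference was 3.73 points, and 1.02 points with each distinct sequence counted once. Reads of 31 bases or longer made up 3.38% against 1.14%. The 134 tRNA-like sequences with at least 100 reads had a median of 1.66 relative to all sequences, and 101 of them were at least 2-fold higher. TCCCGTATGGTCTAGTGGCTAGGATACC, second in this library, had 19015 RPM, against 7281 under Luc siRNA and 11287 under Vasa siRNA. TCTTCGGTAGTATAGTGGTCAGTATCCC had 14945 against 10154. Among the piRNA-length leaders without the motif, TAAACGGATGCGATGACGATCGGCTGGTG had 15325 against 18019 RPM and TGACTGCAAAATAGGTGATTCTTGATGC 14190 against 10823.

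Of 4163 sequences, 615 were at least 2-fold higher and 816 at least 2-fold lower under BmAGO3 siRNA, with a median log2 ratio of -0.18. Median-ratio scaling, which took the center to lie at -0.18 and so raised every ratio, gave 751 higher and 642 lower, so that higher sequences made up 53.9% of the changed ones in place of 42.98%. These counts include tRNA-like sequences. The 5 highest were long sequences of 36 to 39 bases. All of them were tRNA-like except the one at least 43.3-fold higher. That one differs by a single base from the tRNA-like sequence that was at least 62.3-fold higher. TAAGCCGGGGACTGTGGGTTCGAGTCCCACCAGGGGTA, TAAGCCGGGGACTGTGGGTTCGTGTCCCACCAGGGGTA and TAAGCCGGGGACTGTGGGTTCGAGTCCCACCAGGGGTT were unlisted under Luc siRNA and at least 62.3-fold, 43.3-fold and 36.7-fold higher. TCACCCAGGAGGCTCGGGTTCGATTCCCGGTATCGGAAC was at least 57.5-fold higher, and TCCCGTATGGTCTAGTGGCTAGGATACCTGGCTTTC was 30.7-fold higher (22.9 to 41.9). Summed over forms with the same first 20 bases, the 3 sequences that begin with TAAGCC were 12.3-fold higher together, and the other 2 were 5.77-fold and 3.18-fold higher.

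The lowest sequences under BmAGO3 siRNA were TACAGACTATTCCGAGCCCCGACATCGG, 51.0-fold lower (28.3 to 103), and TATCGGAACGAACGGTTCGACAAGTAGG, 30.7-fold lower (16.4 to 64.7). TTTCGTTCTTCGGTTTGCCCGGCTTGG, AAACGACCCTCGTCAAATGTCACTCGAGG and TGTAATCTAACGGATTCAAATCTGGACG were unlisted there and at least 35.9-fold, 27.3-fold and 26.1-fold lower. All 5 end in G. Summed over forms with the same first 20 bases, TACAGACTATTCCGAGCCCCGACATCGG was 3.44-fold lower, TATCGGAACGAACGGTTCGACAAGTAGG 2.13-fold lower, and the other 3 were 3.26-fold, 1.62-fold and 1.88-fold lower.

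The Vasa siRNA and BmAGO3 siRNA comparisons share the Luc siRNA library. Across 3962 sequences listed in all 3 Flag-Siwi libraries with at least 100 reads in each comparison, which are not independent replicates, the log2 ratios had a Pearson r of 0.610, and a simulation with no effect and the shared Luc library gave 0.614. The covariance was 0.650, against 0.0228 in the simulation. Relative to the median, 300 sequences were at least 2-fold lower and 136 at least 2-fold higher under both siRNAs. The same 100 simulations, which hold counting error and no other variation of the Luc siRNA library, gave 0 in each direction. Independent lists of these sizes would share 93.9 and 40.6, a value that leaves out the shared library. The single Luc siRNA library could not be split, and part of the excess over either may come from it.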

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

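The tests on tRNA-like reads and on last bases were chosen after the results were seen; those on partners within the BmAGO3 siRNA library were written before, except the one that leaves out sequences by their first 20 bases.

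Some reads lay outside the comparisons. Of the 20 insect microRNAs looked for, miR-306, let-7 and miR-100 were listed, and the other 17 were not listed in any library. miR-306 had 285 reads (84.4 RPM) under Vasa siRNA and 283 reads (190 RPM) under BmAGO3 siRNA, against 48 (36.5 RPM) under Luc siRNA. let-7 had 36 reads (10.7 RPM) under Vasa siRNA and 29 reads (19.4 RPM) under BmAGO3 siRNA, and miR-100 had 13 reads (3.85 RPM) and 21 reads (14.1 RPM). Both were unlisted under Luc siRNA, where each unlisted form could still have 9 reads. Over the forms listed in any library, the most that Luc siRNA could hold was 63.9 RPM for miR-306, 13.7 RPM for let-7 and 6.85 RPM for miR-100, so let-7 and miR-100 under Vasa siRNA were not above it. None of the 3 was listed in the untreated libraries. Reads under 18 bases made up 1.14% of the Vasa siRNA library, above the 0.420% of the Luc siRNA library. Uncalled bases were found in 462 reads of untreated Siwi and 3122 reads of untreated BmAGO3, and in 0 reads of the Flag-Siwi libraries.

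tRNA-like reads were a larger share of the Flag-Siwi libraries than of untreated Siwi. Longer reads kept in the Flag-Siwi lists do not account for it, since among reads of 24 to 29 bases the share was 6.46% under Luc siRNA and 0.224% in untreated Siwi, a ratio of 28.9. The untreated share is near the 0.192% found with shuffled bases at all lengths, and the Luc siRNA share is above the 0.211% found there. Full-length fragments up to the anticodon loop, taken as 31 bases or longer, do not account for it either. They were 3.88% of the tRNA-like reads of the Luc siRNA library. Read length cannot tell whether the shorter reads came from such fragments, so that source is not excluded. The Flag tag, the siRNA treatment, the antibody and the library batch also stay open, because 0 libraries had the tag or an siRNA without the other.

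More Flag-Siwi sequences had a partner in their own library under BmAGO3 siRNA than under Luc siRNA. A longer list of sequences in the BmAGO3 siRNA library does not account for it: with 22101 sequences in each list the difference was 2.72 points (2.14 to 3.30). Sequences with a tRNA motif do not either, though tRNA fragments without a motif may remain. Without the motif sequences the difference was 3.36 points (2.78 to 3.94). Sequences whose first 20 bases were listed for BmAGO3 and not for Siwi are not the whole cause, since without them it was 1.61 points (1.13 to 2.09); a part is not excluded. BmAGO3-type sequences that enter Flag-Siwi were looked for in another way as well, and the predicted ratio of at least 2 was not found. Of the 794 sequences partnered under BmAGO3 siRNA alone, 14.0% shared their first 20 bases with the untreated BmAGO3 library. Among 20321 unpartnered ones it was 12.04%, a ratio of 1.16 (0.974 to 1.39). A smaller contribution is not excluded. As exact sequences, 1.01% against 1.66% were listed for BmAGO3 and not for Siwi. The intervals of these partner shares count forms with the same 5′ end as independent, so they can be too narrow. Library-to-library variation and an effect of the BmAGO3 siRNA were not tested, with 1 library per siRNA.

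Sequences at least 2-fold lower under both siRNAs ended in G more often than other sequences, in 31.2% of 356 against 13.2% of 3474. These are sequences of 24 bases or longer with at least 100 reads in each comparison, unlisted ones included and tRNA-like ones left out. Forms of abundant sequences that differ by G at the last base were 10.3 times as frequent under Luc siRNA as under BmAGO3 siRNA in the median of 40 sequences (quartiles 3.24 and 15.6). This restates the difference and does not decide on base changes to G at the last base in the Luc siRNA library, since fewer such forms under the other siRNAs would give the same ratio; untreated Siwi had 8.98 such reads per 100, above the 4.48 of Luc siRNA. Whether these are 3′-end variants of piRNAs whose other forms did not fall was not decided: the lower of the median log2 ratios of their forms not ending in G, relative to all 5′ ends, was -0.75. An effect of the Vasa and BmAGO3 siRNAs on 3′ ends cannot be told apart from a property of the control, because there was 1 Luc siRNA library.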

How the results depend on the processing

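Leaving out tRNA-like sequences, thinning to the smallest library without grouping by the first 20 bases, and every alternative for tRNA-like reads were chosen after the data were seen. No paired analysis was possible because each group has 1 library. Requiring 10 reads moved nothing, since no listed sequence has fewer, and thinning the untreated BmAGO3 list moved nothing for Flag-Siwi, since it is the shorter list. Pairing over 16 bases by position and the alternatives for transposon origin were not run, for lack of a genome. Shares, ratios and mean lengths count as moved when they leave the main counting interval, which is narrow at these depths, class medians when they leave the 95% order-statistic interval of the main one, and counts of sequences when they differ by more than 1.5 times. Listed reads and the 10-read minimum limit partner and sharing values, and the cause of each shift was not tested. Of 129 values for named sequences under the abundance alternatives, 90 stayed in their counting interval, 39 moved and 0 changed direction.

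For BmAGO3 against Siwi, the 1U difference was -54.0 points with each sequence counted once and -54.8 without the 10 most abundant; 10A was 48.9, 50.1 and, thinned, 50.1. For Vasa siRNA, 1U reversed to -1.34 with each sequence counted once and was 1.35 at 24 to 32 bases, 0.722 without the 10 most abundant, 0.859 without tRNA-like sequences and 1.68 thinned; 10A was -1.07 at 24 to 32 bases, -0.394 without tRNA-like sequences and -1.70 thinned. For BmAGO3 siRNA, 1U was -4.59 with each counted once, -1.70 without the 10 most abundant, -1.87 without tRNA-like sequences and -0.464 thinned; 10A was 2.75, 1.59, 3.73 and 0.595, and 1.14 at 24 to 32 bases. For Luc siRNA against untreated Siwi, 1U was -5.36 with each counted once, -2.22 at 24 to 32 bases, -2.94 without the 10 most abundant, -3.09 without tRNA-like sequences and -2.14 thinned; 10A was -0.890, -5.41, -3.80, -3.73 and -5.84.

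The mean length difference for BmAGO3 against Siwi was -1.02 bases with each sequence counted once, -0.949 without the 10 most abundant and -0.896 thinned. For Vasa siRNA it was -0.231, -0.110 and -0.0498, and -0.128 without tRNA-like sequences. For BmAGO3 siRNA it was 0.144 without tRNA-like sequences. For Luc siRNA against untreated Siwi it was 0.575 with each counted once, 0.519 without the 10 most abundant, 0.535 without tRNA-like sequences and 0.571 thinned.

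The tRNA-like difference for Vasa siRNA, BmAGO3 siRNA and Luc siRNA against untreated Siwi was 0.282, 1.02 and 1.01 points with each sequence counted once, 3.19, 8.25 and 6.64 at 24 to 32 bases, 0.991, 3.73 and 3.65 without the 10 most abundant, and 4.46, 9.80 and 7.25 thinned.

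Weighted by reads, 32.5% of Siwi had BmAGO3 partners and 37.7% of BmAGO3 had Siwi partners; thinned, 18.6% and 30.3%. The Vasa siRNA difference in BmAGO3 partners reversed to 0.112 points by reads and 2.26 thinned. Its own-library difference was 5.77 by reads, 0.470 with equal lists and reversed to -0.598 thinned. The BmAGO3 siRNA difference in BmAGO3 partners was -4.14 by reads and -1.33 thinned, and its own-library difference was 4.64 by reads.

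By the first 20 bases, shared reads were 35.9% of Siwi and 39.3% of BmAGO3 (25.4% and 40.7% thinned), and 73.4% of Luc siRNA and 81.2% of untreated Siwi (74.9% and 77.5% thinned). The ratio for BmAGO3-only sequences, BmAGO3 siRNA over Luc siRNA, was 3.12 by the first 20 bases, 3.66 when also thinned, 2.83 without tRNA-like sequences, 2.48 thinned alone and 2.70 for BmAGO3 sequences with at least 100 reads, a limit also chosen after the data were seen.

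Without a read minimum, among sequences listed in both libraries, those higher and lower numbered 260 and 754 for BmAGO3 against Siwi and 1492 and 2393 for BmAGO3 siRNA; they numbered 677 and 4821 for Vasa siRNA and 1147 and 2859 for Luc siRNA against untreated Siwi. Higher sequences thus made up 25.6%, 38.4%, 12.3% and 28.6% of those changed. These counts cover other sets of sequences by construction. In every comparison the first library had more listed reads, so its list reaches lower RPM. This favors lower ratios, so the direction of these counts cannot be told apart from an effect of depth. For Vasa siRNA, median-ratio scaling gave 1236 higher and 584 lower, and TMM 1122 higher. The log2 values that median-ratio scaling and TMM subtracted, which raised the ratios, were -1.34 and -1.42 for BmAGO3 against Siwi and -0.59 and -0.62 for Luc siRNA against untreated Siwi. Class medians relative to all sequences without a read minimum reversed under Vasa siRNA to -0.067 for BmAGO3-only and 0.063 for Siwi-only sequences and moved to 0.80 for tRNA-like sequences there. Under BmAGO3 siRNA they moved to 1.04 for tRNA-like and 0.89 for BmAGO3-only sequences. The lower RPM floor of the first library may bear on these medians as well. By the first 20 bases, the tRNA-like and Siwi-only medians under Vasa siRNA were 0.80 and -0.028, and the BmAGO3-only and Siwi-only medians under BmAGO3 siRNA were 1.72 and -0.13.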

Other observations

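All values here were chosen after the results were seen. The BmAGO3-only sequences found in Flag-Siwi mostly carried 10A, as the BmAGO3 list they were drawn from did. Leaving out tRNA-like sequences, 10A was found in 75.2% of 274 such sequences under Luc siRNA, 74.2% of 548 under Vasa siRNA and 78.5% of 576 under BmAGO3 siRNA, and in 79.7% of all sequences of the untreated BmAGO3 library. The 3 sequences named next are among the 10 of the set with most reads under BmAGO3 siRNA. AAACTGTTTACCATCCAAATTCGATTGTC, with 41 reads in untreated BmAGO3, had 748 RPM, against 287 under Luc siRNA, a ratio of 2.61 (2.32 to 2.94). ATGCTGAAAAGATTACTGATGAATCTGC, with 2907 reads in untreated BmAGO3, was 2.81-fold higher (2.32 to 3.41), and TACGATATGTTGAAAAAGTTGGACAAA, with 278 reads there, was 10.4-fold higher (6.92 to 16.4), from 25 reads under Luc siRNA. The latter was the largest of the 10 ratios, and the other 9 lay between 1.83 and 3.53. It was also higher under Vasa siRNA, with 42.03 RPM against 19.03 under Luc siRNA, but most of the 10 were lower there. Of the others named, the one with 41 reads in untreated BmAGO3 had 313 RPM under Vasa siRNA against 287 under Luc siRNA. The one with 2907 reads had 55.9 against 109.6.

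The last base differed between libraries. Among reads of 24 bases or longer, G was last in 23.4% of untreated Siwi, 21.3% of untreated BmAGO3, 16.5% of Luc siRNA, 12.05% of Vasa siRNA and 10.9% of BmAGO3 siRNA reads. For 58 sequences with at least 1000 reads under both Luc and BmAGO3 siRNA, forms with G in place of the last base were counted. Unlisted forms counted as 0 reads, so these values can be too low. The G forms had 8.98 reads per 100 reads of the sequence in untreated Siwi and 0 in untreated BmAGO3. They had 4.48 under Luc siRNA, 0.306 under Vasa siRNA and 0.261 under BmAGO3 siRNA. For U, A and C, sequences that already end in that base were left out. Forms with U in that place had 14.7, 14.5 and 15.6 under Luc, Vasa and BmAGO3 siRNA, forms with A 1.29, 1.55 and 2.06, and forms with C 61.1, 49.3 and 66.6. In untreated Siwi they had 10.6, 0.324 and 19.3. TATCGGAACGAACGGTTCGACAAGTAGG had 12.1 reads per 100 of TATCGGAACGAACGGTTCGACAAGTAGT in untreated Siwi and 9.63, 0.613 and 0.633 under Luc, Vasa and BmAGO3 siRNA.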
